A study of Mus musculus with 6 samples.

How the data were processed

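Replication timing was read from whole-genome sequencing depth of proliferating mouse myeloid cell lines that had been immortalised with HoxB8 and selected in GM-CSF. Cells in S phase hold more copies of early replicating DNA than of late replicating DNA, so depth along the genome of an unsorted, growing culture follows the order of replication. Per the labels, the series held 3 wild-type samples and 3 samples that lacked both Recql4 and Klhdc3. Libraries were DNBSEQ paired-end libraries with reads of 150 bp and a target of 30-fold coverage, per the labels' protocols. The depth that each library reached was not given in the sources used here, so no counting interval was computed.

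The authors deposited 2 headerless tables over 237602 windows of at least 10000 bp (median 10041 bp), each with 4 position columns and 6 columns of values. The genome build was mm10 and Picard 2.23.9 was among the tools, per the submitters' processing notes. TIGER, a method that infers timing from sequencing depth, was named in the series title. The aligner, GC correction, window filter and smoothing settings were not given in the sources used here. The first table held a normalised DNA copy level, here called the raw level, with autosomal medians between 1.96 and 1.98 and X medians between 0.931 and 0.943. The second table held a smoothed timing score, and the deposited score columns each had a mean of 0 and an SD of 1 over the autosomal windows, so that a higher score stood for earlier replication. Scaling each profile in this way removed differences in overall amplitude, and any large stretch that stood apart in a profile entered its mean and SD. Chromosome 19 carried no value (NaN) in either table, and chromosome 12 carried none in 2 of the 6 columns.

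The 6 value columns had no names, and no label tied a column to a sample. They were therefore treated as 6 unassigned profiles, called A to F in the order of the columns, and no comparison between genotypes was made. The limma tests, exact permutation tests and rules for named regions that had been fixed before the data were examined all needed the genotype of each column and were not run. In their place each quantity was given per profile or as its median and range over the 6 profiles. For the same reason the rule for named genes, which had ranked genes by p, could not be applied. It was replaced by the earliest and the latest member of each gene list by median score over the profiles, together with Recql4 and Klhdc3. No column of values was left unused.

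Windows were averaged into 100-kb bins, each profile over its own valued windows, and bins with at least 3 such windows in each of the 6 profiles were kept, which gave 21473 autosomal bins and 22920 bins with X. Chromosomes 12 and 19 therefore gave no bin, and entered no bin count, variable region or gene-list score. Genes came from the RefSeq annotation of the same build, with 21631 protein-coding genes. That annotation was used without strand, so each gene was placed at its midpoint and took the score of the nearest window within 50 kb. The 15 gene lists were fixed before the data were examined, and a list's score was the mean over the distinct bins that held its members. Each list was set against 10000 random lists of as many autosomal genes as it had distinct bins, each gene with the score of its bin. Genes of a random list could share a bin. Random lists were first drawn bin by bin. On simulated lists of random genes, 20 of 200 then lay above the 97.5th percentile and 2 below the 2.5th, because genes are concentrated in early bins. Drawing gene by gene gave 2 and 6 of 200, and this form was used. Percentiles describe these profiles and are not p-values, and they take no account of members that sit side by side in a cluster.

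Timing amplitude was the mean raw level of the earliest 20% of the autosomal bins minus that of the latest 20%, with both set by the mean score of the 6 profiles. Timing peaks were local maxima with a prominence of at least 0.25 score units on the windows valued in every profile, and peaks of a pair of profiles were shared when they lay within 100 kb. Similarity was Pearson's r across autosomal bins, which are not independent replicates. Noise was the SD of the raw level around a straight-line fit on the score. A bin was called variable when its scores ranged over at least 1 unit among the 6 profiles. Variable bins at most 2 Mb apart were joined into broad stretches where these exceeded 2 Mb and over 50% of their bins were variable, and the remaining ones into local regions of at least 300 kb with gaps of up to 1 bin. Earliest and latest sites were the bins with the most extreme median scores, at least 1 Mb apart. They were sought only on the 12 chromosomes without large shifts listed below, with local regions left out. These definitions, and the naming of the 10 local regions with the widest range and of the 5 earliest and 5 latest sites, were chosen after the data were seen. Some of the genes and regions that these rules select are not reported here.

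The steps were tested on simulated data made from the median profile with noise of SD 0.108 per bin. All 3 broad shifts and all 20 local shifts of 1.5 score units were recovered, and 9 of 20 local shifts of 0.8. With independent noise of this size the outcome at 1.5 followed from the limit of 1, so the simulation checked the joining of bins and not how often differences between real samples pass the limit. Alternatives were quantile normalisation, rescaled raw levels, 500-kb bins, stricter bin filters, other peak and amplitude settings, Spearman's rho and, added after the data were seen, the 12 chromosomes without large shifts (1, 2, 5, 7, 8, 9, 10, 11, 13, 15, 16 and 18), other range limits, another gene position and leaving out each profile in turn. Alternatives that needed genotypes or replicate numbers were not run, and rescaling over autosomes was already the deposited scale. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.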

Results

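Replication timing was measured in 6 samples of HoxB8-immortalised mouse myeloid cells, 3 wild-type and 3 lacking both Recql4 and Klhdc3. Recql4 encodes a RecQ family helicase that acts in the initiation of DNA replication, and Klhdc3 encodes a substrate receptor of CUL2 ubiquitin ligases. Per the labels, the cells divided every 15 to 18 hours and over 25% of the cells in culture were in S phase. Whether the samples of a genotype came from separate lines or cultures was not given in the sources used here. The design set the double mutant against the wild type, asking whether the order of replication along the genome differed. The 6 profiles carried no sample names, so the values below are given per profile, A to F, without a comparison of genotypes. No profile is a known replicate of another.

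The targeted genes themselves lay in early replicating DNA in the 6 profiles. At Recql4 (chromosome 15, 76703553 to 76710616, mm10) the raw copy level over the 2 windows that overlap the gene was 2.18, 2.19, 2.12, 2.06, 2.15 and 2.21 in profiles A to F, with timing scores of 1.35, 1.40, 1.33, 1.25, 1.33 and 1.35. At Klhdc3 (chromosome 17, 46674550 to 46680930) the raw level was 2.20, 2.20, 2.14, 2.17, 2.11 and 2.17, and the scores were 1.11, 1.15, 1.30, 2.14, 1.21 and 1.05. The Klhdc3 score of profile D belonged to a stretch of chromosome 17 with a higher mean score in that profile. The raw level of D at the gene itself lay within the range of the other profiles. These windows reach from 76696491 to 76716577 and from 46667508 to 46687735, beyond both ends of each gene. How much of each gene was deleted was not given in the sources used here, so the levels did not check the genotype of any profile.

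Early replicating DNA was rich in genes and late replicating DNA was poor in them. From the latest to the earliest 20% of the autosomal bins, protein-coding genes numbered 2.14, 3.99, 6.37, 10.9 and 19.02 per Mb, an 8.87-fold rise. Of the 18018 autosomal genes with a score, 76.5% scored above 0 in each of the 6 profiles and 15.3% below 0 in each. The earliest and latest sites were sought only on the 12 chromosomes without large shifts, with local regions left out. Among the earliest was the bin of Med26, a Mediator subunit, with Tmem38a and Smim7 on chromosome 8 (72500001 to 72600000). Its median score was 2.12 (range 2.03 to 2.17). Bins with Slc26a6, Celsr3 and Nckipsd on chromosome 9 (108800001 to 108900000, median 1.95) and with Taf15, Mmp28 and Rasl10b on chromosome 11 (83400001 to 83500000, median 1.92) came next. Of the 5 latest sites, 4 lay on chromosome 1, among them the bin from 49900001 to 50000000 with a median of -2.25, and the other lay on chromosome 10 (47800001 to 47900000, median -2.14). None of these 5 bins overlapped a protein-coding gene.

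The raw copy level of the earliest 20% of bins exceeded that of the latest 20% by 0.428, 0.392, 0.342, 0.384, 0.422 and 0.416 in profiles A to F, a median ratio of 1.23 (range 1.19 to 1.25). Raw levels scattered around the smoothed profile with an SD of 0.121 to 0.127 per window. The median raw level of the X chromosome was between 47.4% and 47.6% of the autosomal median. Chromosome 12 had median levels of 1.97, 1.98, 2.02 and 2.20 in profiles A, B, C and F, and carried no value in D and E. Chromosome 17 stood at 2.05 in profile D and between 1.96 and 1.99 in the others. Chromosome 3 stood at 1.86 in profile E and 1.89 in D, against 1.92 to 1.94 in A, B, C and F.

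**Figure D1:**
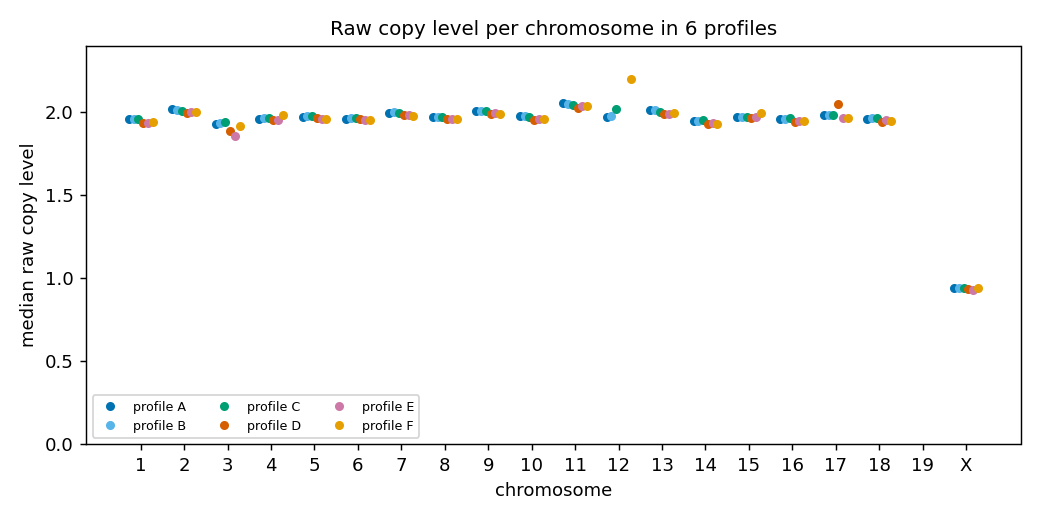
Median raw DNA copy level (y axis, no unit, about 2 for autosomes) of each chromosome (x axis), with 1 point per profile A to F and no point where a profile carried no value. Chromosome 12 of profile F stands at 2.20, chromosome 17 of profile D at 2.05 and chromosome 3 of profile E at 1.86, while X lies between 0.931 and 0.943.

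Granulocyte genes and housekeeping genes replicated earlier than random gene lists in each profile. The granulocyte list, genes of neutrophil granules and of the granulocyte lineage, had a median score of 1.16 (range 1.01 to 1.22) at percentiles 98.6 to 99.6 of 10000 random lists, and its 13 measured members scored above 0 in each profile. Its earliest member was Elane, which encodes neutrophil elastase (chromosome 10, 79886312 to 79888216, median 1.63), and its latest was S100a9, a calprotectin subunit, at 0.68. The housekeeping list scored 1.13 (0.98 to 1.14) at percentiles 98.9 to 99.5, from Ppia, cyclophilin A, at 1.55 to the ribosomal protein gene Rplp0 at 0.80. Both lists were near the limit of 97.5 in some settings: the lowest percentile of the granulocyte list was 97.47 on rescaled raw levels, and that of the housekeeping list was 97.42 in 500-kb bins and 96.89 on the chromosomes without large shifts.

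Macrophage and monocyte genes had a median list score of 1.02 (0.95 to 1.04) at percentiles 96.0 to 98.9, below the limit in part of the profiles. Spi1, a transcription factor of the myeloid lineage, was their earliest at 1.52 (1.32 to 1.58), and 12 of the 13 measured members scored above 0 in each profile. The RecQ helicases scored 1.25 (1.20 to 1.31) over 4 measured members at percentiles 94.7 to 98.5, with Blm, the Bloom syndrome helicase, at 1.66 and Wrn, the Werner syndrome helicase, at 0.53.

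Genes of origin licensing and firing did not stand apart from random lists. Their list scored 0.75 (0.63 to 0.78) at percentiles 71.6 to 79.5, and 26 of its 29 members scored above 0 in each profile. Donson, a factor of replication initiation and fork stability, was the earliest at 1.56, and Mcm3, a subunit of the replicative helicase, the latest at -0.46, although its bin stood at 0.18 on rescaled raw levels. The CUL2 ligase list scored 0.88 (0.78 to 0.95) at percentiles 70.8 to 85.6, but 0.55 at percentiles 37.4 to 48.3 over the 3 bins on chromosomes without large shifts, and 1.19 at percentiles 92.4 to 96.7 on rescaled raw levels. Its RING subunit Rbx1 was early at 1.47 and its scaffold Cul2 (chromosome 18, 3382970 to 3436700) near the middle at -0.13, or 0.47 on rescaled raw levels. Histone genes scored 0.72 (0.57 to 0.82) at percentiles 39.9 to 86.3, from H2ac20 at 1.36 to H2ac11 at 0.36, and their 49 measured members were above 0 in each profile.

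Genes of other blood lineages also lay inside the random range. The lymphoid list scored 0.70 (0.58 to 0.76) at percentiles 54.9 to 69.5, and its latest member was the T-cell transcription factor gene Gata3 at 0.05, or -0.30 on rescaled raw levels. The erythroid and megakaryocyte list scored 0.62 (0.48 to 0.65) at percentiles 39.4 to 51.6. Within it Epor, the erythropoietin receptor gene, was early at 1.25, and the globin gene Hbb-bt (chromosome 7, 103812524 to 103813923) was late at -0.76 (-0.87 to -0.58). Stem and progenitor genes scored 0.42 (0.29 to 0.47) at percentiles 10.1 to 23.7, from Gata2, a transcription factor of stem and progenitor cells, at 1.48 to Meis1, a cofactor of Hox proteins, at -0.89. The 39 Hox cluster genes scored 0.26 (0.22 to 0.42) at percentiles 6.92 to 19.9, from Hoxc4 at 0.87 to Hoxb9 at -0.17. The Hox score depended on the setting, at -0.09 and percentiles 0.24 to 2.41 on rescaled raw levels and at 0.53 and percentiles 34.6 to 51.5 in 500-kb bins. Clustered protocadherin genes, which encode neuronal adhesion proteins, scored 0.24 (0.16 to 0.38) at percentiles 5.18 to 26.6, with Pcdhgc5 at 0.71 and Pcdhb8 at -0.08, a median that was 0.05 with profile A, B or C left out. On rescaled raw levels the protocadherin score was 0.07 at percentiles 1.12 to 10.8.

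Genes of very long fragile sites, neuronal genes and olfactory receptor genes replicated later than each of the 10000 random lists in the 6 profiles. The list of very long genes at common fragile sites had the lowest score, -0.89 (-1.04 to -0.80), and 9 of its 11 measured members scored below 0 in each profile. Lrp1b, a lipoprotein receptor gene that covers 40595290 to 42653598 of chromosome 2, was the latest at -1.42 (-1.43 to -1.34), and Exoc4, an exocyst subunit, the earliest at -0.10, or 0.06 when placed at its lower coordinate. The neuronal list scored -0.61 (-0.70 to -0.40), with 5 of its 11 measured members below 0 in each profile, 1 above 0 in each and 5 mixed, from the synaptic fusion gene Snap25 at 0.32 to the glutamate receptor subunit gene Gria2 at -1.39. With the chromosomes of large shifts left out, the neuronal list kept 5 bins with a score of -0.14 at percentiles 1.61 to 4.74. The 1017 measured olfactory receptor genes, which are silent outside sensory neurons as a rule, occupied 311 bins with a score of -0.44 (-0.50 to -0.41), or -0.09 over 105 bins of 500 kb, where it still lay below the random lists. Of these genes 737 scored below 0 in each profile and 203 above, from Olfr1118 on chromosome 2 at -1.91 to Olfr225 on chromosome 11 (1.43 to 1.55).

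Several named genes stood elsewhere on rescaled raw levels, which are unsmoothed means of the 100-kb bin. S100a9 stood at 1.41, Rplp0 at 1.25, Wrn at 0.94, Pcdhgc5 at 1.12 and Pcdhb8 at -0.46. Meis1 stood at -0.43, Gria2 at -0.88, Hbb-bt at -1.17 and Hoxb9 at -0.66. Placed at its lower coordinate, Wrn scored 0.27.

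**Figure D2:**
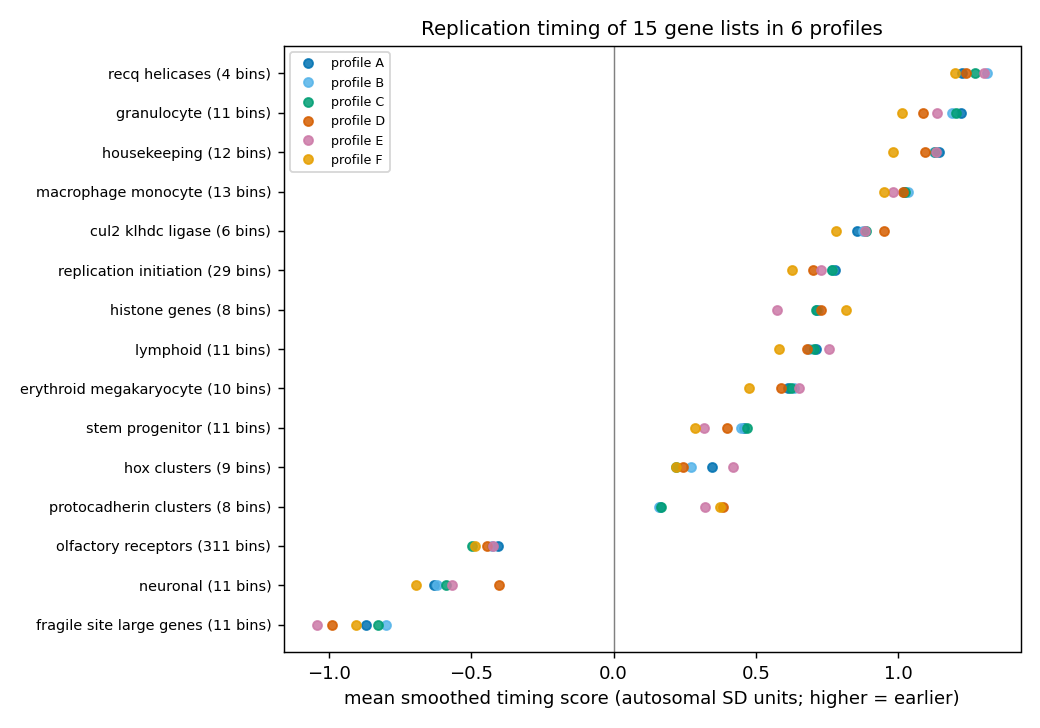
Mean smoothed timing score (x axis, in autosomal SD units, higher is earlier) of each of the 15 gene lists (y axis, with the number of 100-kb bins), with 1 point per profile A to F. Fragile-site, neuronal and olfactory receptor lists lie below 0 in each profile, and the other 12 lists above.

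The order of replication was similar among the profiles. Pairwise Pearson r across autosomal bins had a median of 0.950 (0.928 to 0.996) over 15 pairs, and 0.977 (0.965 to 0.995) on the 12 chromosomes without large shifts. Timing peaks numbered 811, 807, 814, 741, 739 and 735 in profiles A to F, and a median of 81.4% (76.1% to 89.2%) of the peaks of a pair were shared within 100 kb. Scores ranged over less than 0.5 units among the 6 profiles in 85.9% of the bins and over at least 1 unit in 1270 bins (5.91%). Of these variable bins, 1120 lay in 6 broad stretches and 137 in 21 local regions. Without profile D, the share of variable bins fell to 3.20%.

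Each broad stretch set 1 or 2 profiles apart on chromosome 3, 4, 14 or 17. Chromosomes 12 and 19 held no bin valued in all profiles and were not searched for stretches or local regions. On chromosome 3 the stretch from 3100001 to 48100000, with Naaladl2 and the synaptic adhesion gene Nlgn1 among its 145 protein-coding genes, had mean scores of -2.16 in profile E and -1.47 in D, against -0.67 to -0.70 in A, B, C and F. Its raw level in E was 87.1% of the median of the other profiles. On chromosome 4 the stretches from 37600001 to 40000000, 48400001 to 56800000 and 62600001 to 73200000 stood 2.34, 2.49 and 2.55 units higher in profile F, at raw levels of 120%, 120% and 121% of the others. Profile F carried no value in 1715 windows of chromosome 4, against 214 to 229 in the other profiles. Missing bins could split a stretch, so these chromosome 4 stretches may not be separate events. The last of these chromosome 4 stretches held Astn2, a neuronal migration gene, Pappa and Cdk5rap2. On chromosome 14 the stretch from 92600001 to 99800000, with the protocadherin gene Pcdh9, Klhl1 and the transcription factor gene Dach1, scored -2.50 in profile D and between -1.13 and -0.91 in the others. On chromosome 17 the stretch from 40500001 to 94900000, with 356 genes that included Klhdc3 and Alk, scored 0.83 in profile D and between -0.29 and -0.13 in the others.

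**Figure D3:**
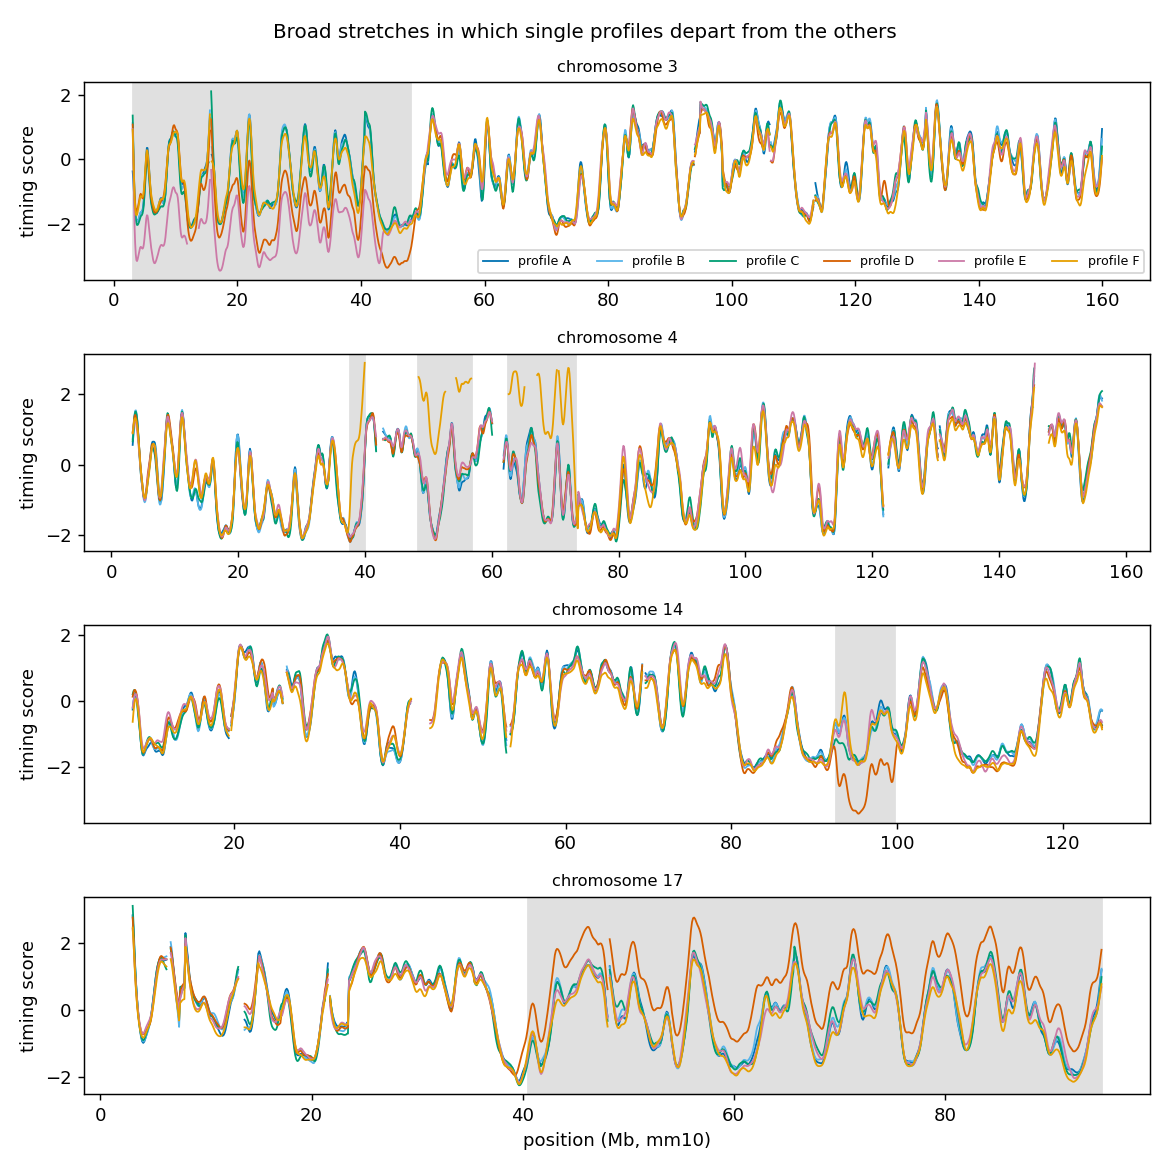
Smoothed timing score (y axis, higher is earlier) along chromosomes 3, 4, 14 and 17 (x axis, position in Mb, mm10), with 1 line per profile A to F, gaps where no value was carried, and grey bands over the 6 broad stretches. Profiles E and D lie below the others on chromosome 3, F lies above on chromosome 4, and D lies below on chromosome 14 and above on chromosome 17.

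The local regions measured 300 to 1400 kb. The widest range was on chromosome 13 from 119600001 to 119900000, with Nim1k, the chemokine gene Ccl28 and Zfp131, where profiles A, B and C scored 4.24, 4.57 and 4.88 and D, E and F scored 0.80, 1.24 and 0.97. There, a single window from 119609747 to 119620655, at Tmem267, had raw levels of 14.2, 13.8 and 13.7 in A, B and C and carried no value in the others. Over the 22 windows of that region valued in each profile, the raw levels were 2.18, 2.18, 2.15, 2.07, 2.15 and 2.13 in A to F. On chromosome 6 from 138300001 to 139700000, with Lmo3 and Pik3c2g, profile E scored 3.11 and the others -0.79 to -0.66. The raw level of that region in E was 130% of the median of the other profiles. Profile E carried no value in 1138 windows of chromosome 6, against 64 to 69 in the other profiles. At Macrod2, a fragile-site gene, on chromosome 2 from 141800001 to 142500000, scores in profiles A to F were 0.48, 0.46, 0.33, -0.28, -0.67 and -0.74.

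Another named local region held Nckap5 on chromosome 1 (126100001 to 127100000), at 0.54, -0.06, -0.13, -0.61, -0.66 and -0.80 in profiles A to F. The growth hormone receptor gene Ghr lay in a region on chromosome 15 (3100001 to 3800000), at -0.27, -0.33, 0.18, 0.78, 0.88 and 0.05. The region of the neuronal adhesion gene Tenm4 on chromosome 7 (95700001 to 96400000) scored 0.04, 0.08, 0.09, 0.44, -0.0018 and -0.77. Regions on chromosome 7 (71200001 to 71900000) and chromosome 8 (5800001 to 6600000) overlapped no protein-coding gene. The former scored 0.20, 0.20, 0.18, -1.19, -1.04 and -0.93 in A to F, and the latter -1.51, -1.54, -1.56, -0.94, -1.13 and -0.16. The number of local regions was 13 without profile F and 35 on rescaled raw levels, and 20 of the 21 regions overlapped a local region or broad stretch on those levels.

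**Figure D4:**
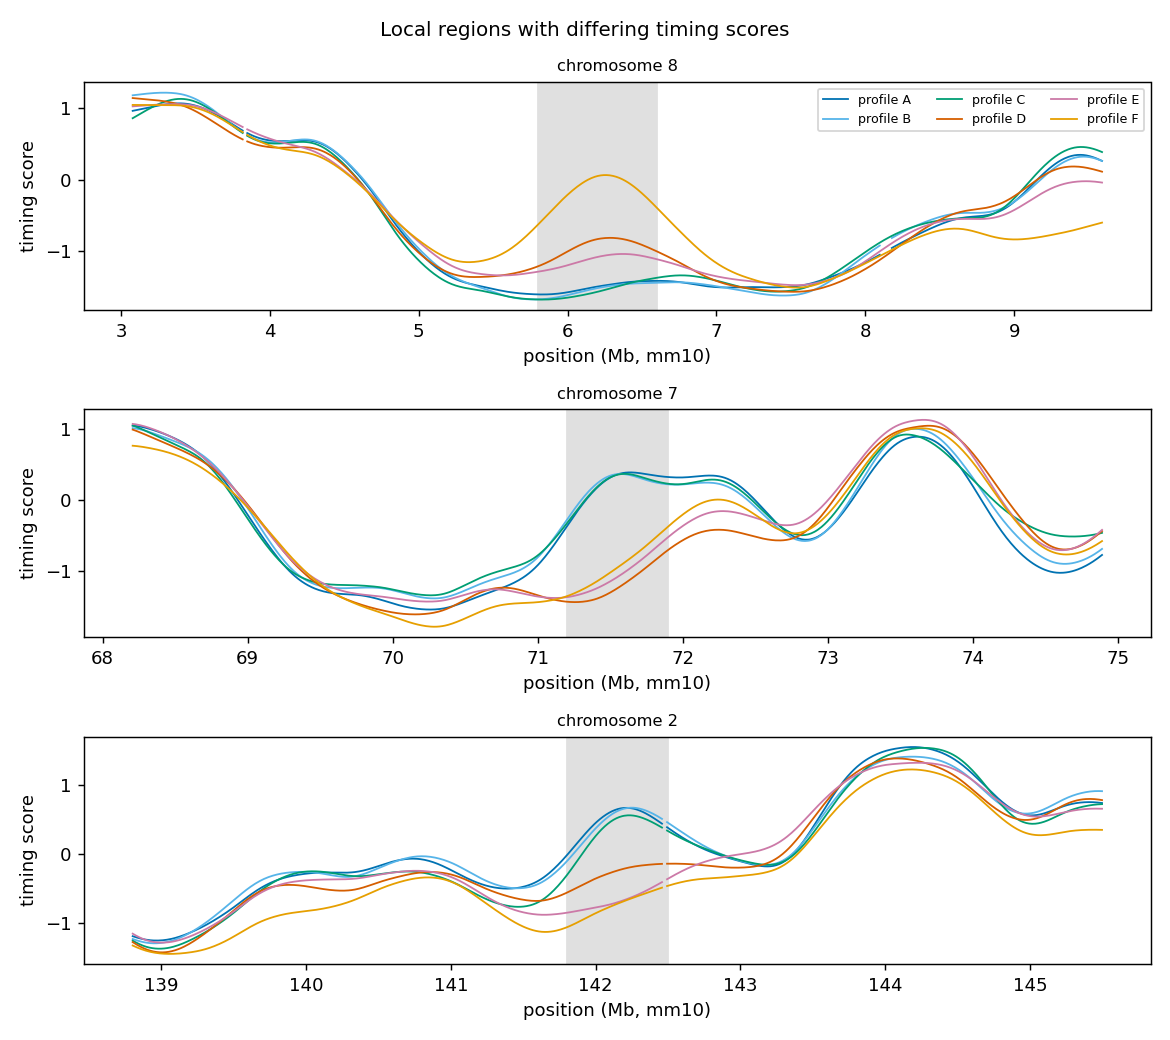
Smoothed timing score (y axis, higher is earlier) along parts of chromosomes 8, 7 and 2 (x axis, position in Mb, mm10), with 1 line per profile A to F and grey bands over a local region each. Within the bands the scores range over 1.40, 1.39 and 1.22 units, while the lines mostly run closer together on the flanks. The flank of chromosome 8 includes another local region without a band (9200001 to 9600000, range 1.09).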

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

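The alternatives that left out a profile or the chromosomes with large shifts, added X to the correlations or peak counts, took mean raw levels of chromosomes, used other range limits or another gene position, rescaled over the chromosomes without large shifts, or drew random lists bin by bin were chosen after the data were seen, and the others before. No paired analysis was possible because the columns carry no replicate number. With profiles left out not counted, 54 of 75 values of gene lists under alternatives moved by less than the spread between profiles, and 113 of 160 values of named genes did. The depth behind each window is unknown, so what depth limits was seen only as the scatter of raw levels, which was 0.119 by the median absolute deviation and 0.0443 per 100-kb bin. Signs turned on rescaled raw levels for the Hox list (-0.0927), Cul2 (0.47), Gata3 (-0.30) and Mcm3 (0.18), for Gata3 after rescaling over the chromosomes without large shifts (-0.00976), for Exoc4 at its lower coordinate (0.0603) and for Pcdhb8 with profile A, B or C left out (0.0505, against -0.21 with D, E or F left out). The median correlation was 0.977 on the chromosomes without large shifts and 0.987 with X. Mean scores of X lay between -8.53 (profile C) and -6.52 (profile F), at raw medians of 0.931 to 0.943. The value with X therefore also held this offset from the autosomes, and was not a measure of the order of replication alone. The amplitude was 0.469 between the earliest and latest 10%, which are more extreme by construction. Shared peaks were 60.2% within 50 kb and 87.7% within 200 kb. Variable bins were 14.1% at a range of 0.5 and 2.99% at 1.5. On the chromosomes without large shifts they were 0.786%, or 0.924% when rescaled, and between 3.20% (without profile D) and 5.86% with a profile left out. Local regions numbered 35 on rescaled raw levels, and 13 (without profile F) to 20 with a profile left out. Lists earlier than random lists numbered 1 on rescaled raw levels, 1 in 500-kb bins, 1 on the chromosomes without large shifts and 4 with random lists drawn bin by bin, which favour early lists. The causes of the other shifts were not tested.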

Other observations

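All tests in this part were chosen after the results they bear on had been seen, and no biological explanation was tested against genotype, because the profiles are not tied to samples. Across the bins of the 12 chromosomes without large shifts, profiles A and B correlated at 0.995, A and C at 0.989, B and C at 0.992, D and E at 0.990, D and F at 0.983, and E and F at 0.986. The other pairs lay between 0.965 (C and F) and 0.977 (B and E), so on these chromosomes the profiles fell into the clusters A, B, C and D, E, F. Over all autosomes, with the broad stretches included, E and F (0.928) and D and F (0.930) were instead the lowest of the 15 pairs. Shared peaks followed the same clusters except in D and F. They were 89.2% in A and B, 84.8% in A and C, 85.9% in B and C, 84.5% in D and E and 83.0% in E and F. Pairs across the clusters shared 76.1% (C and F) to 81.6% (A and F), and D and F shared 81.4%. Peak counts lay at 811, 807 and 814 in A, B and C and at 741, 739 and 735 in D, E and F. In most local regions the scores of A, B and C did not overlap those of D, E and F, as at Nckap5 and Macrod2. They did overlap in others, among them those of Ghr, Tenm4 and Lmo3. The regions were picked for a wide range among these same profiles, so such splits are no separate evidence for the clusters. The share of all bins without overlap was not computed. The score of the clustered protocadherin genes was 0.16, 0.16, 0.17, 0.38, 0.32 and 0.37 in A to F, and that of Pcdhb8 was -0.21, -0.23, -0.25, 0.13, 0.05 and 0.13. This split was not particular to protocadherin genes. The origin licensing and firing, granulocyte, macrophage and monocyte, stem and progenitor, and fragile-site lists also did not overlap between the clusters, with A, B and C higher. The remaining lists did overlap. Which samples these profiles came from stays unknown, and the labels name no batch.

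Besides the window at Tmem267, a pair of autosomal windows had raw levels above 3.5 in some profile. On chromosome 17, a window from 3075565 to 3086989 had levels from 4.87 to 5.28 in the 6 profiles. On chromosome 7, a window from 106239211 to 106249405 had 4.04, 3.83, 3.89 and 3.98 in B, C, D and F and carried no value in A and E. Neither window overlapped a protein-coding gene.

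The broad stretches were set against a copy change of the DNA and against a change in timing alone. A timing change alone would keep scores within those seen elsewhere in the same profile, yet 44.5% of the bins on chromosome 3 in E, 38% in the stretches of chromosome 4 from 48400001 and 62600001 in F and 43.06% on chromosome 14 in D lay beyond every bin of the chromosomes without large shifts, local regions left out, which argues against it there. The share was 12.5% in the stretch of chromosome 4 from 37600001 and 8.688% on chromosome 17 in D, at Klhdc3 and Alk. These bins went beyond what a timing change alone would keep, but the mean scores of both stretches lay inside the ordinary span. The outcome was therefore mixed and did not decide on a timing change alone there. The raw level of the chromosome 4 stretch, 120% of the others, was near those of the other chromosome 4 stretches. A copy change would move early and late bins alike, and the slope of the scores on the median of the other profiles was 1.055 in the stretches of chromosome 4 from 48400001 and 62600001, 0.9675 on chromosome 14 and 0.9998 on chromosome 17, consistent with gains in F and D and a loss in D, which may be carried by part of the cells. The slope was 1.413 in the stretch of chromosome 4 from 37600001 and 0.5756 on chromosome 3, at Naaladl2 and Nlgn1, which leaves a copy change open in both.

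The local regions of chromosomes 13 (Nim1k, Ccl28) and 6 (Lmo3, Pik3c2g) stood apart most. In the profiles concerned, 66.67% and 100% of their bins lay beyond every bin of the chromosomes without large shifts, local regions left out, which argues against a timing change alone. On chromosome 13 the smoothed scores of A, B and C fell from 12.7, 13.2 and 15.0 in the window from 119620656 to -4.92, -4.82 and -6.12 in the window from 119886817, while D, E and F stayed between 0.79 and 1.47. With windows that lack a value in some profile left out, the raw levels of the region ranged over 0.1035, within 0.184 for scatter alone, so the smoothing of the single high window at Tmem267 is a candidate explanation of this region. Why that window stood near 14 in A, B and C was not tested. Nor was a copy change of the chromosome 6 region, where the raw level in E was 130% of the median of the other profiles.

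The other 19 local regions held long genes more often than places of similar score. A gene of at least 500 kb lay in 9 of the 19 (among them Nckap5, Macrod2, Tenm4, Sgcz, Csmd1, Auts2, Fam155a and B3galt1), against a mean of 3.32 in random places of the same length and similar score (one-sided permutation p = 0.0019). The score of the place alone is therefore argued against as the cause, and gene density was not matched. Over the 21 local regions the raw levels ranged over 9.929 times the scatter of a region mean in the median, but this scatter is that within a profile, so ordinary differences between samples stay open. A local copy change stays open too, since copy changes in part of the cells may have any size. The highest raw range of the 19 regions was 0.2593. Raw levels on the chromosomes without large shifts spanned 0.518 from the 1st to the 99th percentile, scatter included.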
